A study of Homo sapiens with 2 samples.

How the data were processed

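The measurement was RNA sequencing of poly(A)-selected RNA from cells labelled as DU145, with fragmented RNA copied from random hexamer primers, per the labels' protocols. Whether the libraries kept the strand of the RNA is not given in the sources used here, so a gene and an antisense partner cannot be told apart. The deposited table held whole-number counts per gene for 17249 gene symbols in 2 columns, with no normalization, as judged from the values and the differing column totals. The reads were mapped to the hg19 genome build, per the submitters' processing notes. The aligner, the counting program, the annotation and any filter on genes are not given in the sources used here. No row of the table was at 0 in both columns, and it held no mitochondrial genes. The table named 25 rows like calendar dates, as a spreadsheet writes some gene symbols, and 2 such names were each used by 2 rows. They held 0.227% of the counts in the control library and 0.161% in the si-P53RRA library, were kept in library totals and tallies, and are not named in the text.

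The groups came from the sample labels. The column named for si-P53RRA was matched to the sample with that title, and the column named for the negative-control RNA was taken as the control, since the other sample carries only the name of the cell line. Each group had 1 library, so no dispersion, standard error or p-value was computed, and genes were described by a fixed rule of size. The treatment text is the same for both samples and names only the RNA against P53RRA, so what the control cells received is not given in the sources used here beyond the name of the column.

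Library sizes were scaled with the trimmed mean of M-values in edgeR 4.0.16 under R 4.3.3, with factors of 1.05 for the control library and 0.955 for the si-P53RRA library. The log2 change of a gene was log2(CPM + 0.5) in the si-P53RRA library minus the same in the control library, for 13532 genes with at least 1 CPM in either library. Genes at least 2-fold apart on this scale were tallied. The number of counts of a gene was given an exact Poisson 95% interval, and the ratio between libraries an exact conditional binomial 95% interval. The folds printed with such intervals are ratios of CPM without the pseudocount. Where a library had 0 counts, the fold is a lower bound against 3 counts in that library, which are 0.179 CPM in the control library and 0.263 CPM in the other. The exact 95% interval of 0 counts reaches 3.69 counts. A fold given as "at least" is therefore set by the 3 counts and is not the end of a 95% interval, which would lie lower. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. The 10 most abundant genes held 5.83% of the counts in the control library and 5.40% in the si-P53RRA library.

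Gene lists, 36 in all, were fixed before the data were examined, as were the comparisons, the settings and the rule for named genes, except where a later choice is stated. They cover ferroptosis, iron, glutathione and NRF2 genes, the AKT pathway and FOXO and p53 targets, cell cycle, stress, lipid and energy metabolism, immunity, neighbours of LINC00472, and markers of cell types. The median log2 change of each list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile is a description of these libraries and not a test. Named genes were LINC00472 and G3BP1, the 12 genes with the largest increase and the 12 with the largest decrease among those with at least 5 CPM in either library and 50 counts over both, 12 genes of ferroptosis, AKT and p53 biology chosen beforehand, and at most 4 members per list with the largest log2 change of at least 1 in size. For a list with no such member, the 2 with the largest change were named. Y-linked genes and XIST entered totals and tallies and are not listed. Some genes that the rule names are not reported here.

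Alternatives were total-count, upper-quartile and median-ratio scaling (the last from DESeq2 1.42.0), other filters and pseudocounts, other sizes of change, a requirement that the counting interval exclude 1, and random lists not matched on expression. Added after the data were seen were leaving out genes at 0 in 1 library, setting them at their bound, and a correction of log2 changes by a cubic surface in GC content and log length of the longest transcript. Transcript sequences and gene order came from GENCODE 29, a newer build than the one the authors used, so no coordinates are given. The 12807 genes with a value were 94.6% of those tested. For gene order, 8896 genes with at least 5 CPM in both libraries were cut into 169 runs of 50 neighbours, and the spread of the run medians was set against 1000 shuffled orders.

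The procedure was tested on counts simulated for the comparison of these 2 libraries over 17249 genes. The changed genes were drawn only from those with a mean of at least 5 CPM. Of 50 such genes raised or lowered 2.5-fold, 96.0% were called at least 2-fold apart in the right direction. The same call was made for 100% of 50 at 4-fold, 100% of 50 at 8-fold and 0% of 50 at 1.5-fold. These shares do not cover genes with a lower mean, LINC00472 among them. Of 12975 unchanged genes 0.139% were called, and 95.2% of the ratio intervals covered the true ratio. The counts were simulated with Poisson error only, without variation between cultures. These rates therefore describe counting error and not how often replicate cultures would differ. Of 200 random lists, 4.0% fell outside the middle 95% range, and a list raised 2.5-fold lay at percentile 100. Other computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.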

Results

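The data were poly(A)-selected RNA sequencing counts from 2 libraries, 1 per group, both labelled as DU145, a human prostate cancer cell line of epithelial origin first grown from a brain metastasis. One library was labelled as transfected with 200 pmol of small interfering RNA against P53RRA, with fresh medium after 4 h and another 48 h of culture. The other served as the control, and its data column is named for a negative-control RNA. P53RRA is a long noncoding RNA made from the gene LINC00472. It has been described as a partner of the RNA-binding protein G3BP1 that acts on p53 and on ferroptosis, an iron-dependent death by lipid peroxidation. The control library held 16030207 counts over 16042 detected genes, and the si-P53RRA library held 11942362 counts over 15174 detected genes. Throughout, "higher" and "lower" describe the library labelled si-P53RRA relative to the library labelled control. With no replicates, no test between the conditions was possible, no difference has a replicate check, and the 95% intervals in parentheses cover counting error only.

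The targeted RNA was checked first. LINC00472 had 105 counts in the control library (6.26 CPM) and 6 counts in the si-P53RRA library (0.526 CPM), 11.9-fold lower (5.29 to 33.2). Its log2 change was −2.72 with a pseudocount of 0.5 CPM. A difference of this size was not rare between these libraries: of the 677 genes at similar expression, 108 (16.0%) were lower by as much. Among the genes next to it on chromosome 6, OGFRL1 was 2.22-fold lower (1.76 to 2.82), the potassium channel gene KCNQ5 was 2.45-fold lower (1.79 to 3.39) and SDHAF4, an assembly factor of succinate dehydrogenase, was 2.94-fold higher (1.96 to 4.49). The 5 measured neighbours had a median log2 change of −0.36, at percentile 37.3 of random lists matched on expression. G3BP1 itself was 1.32-fold lower (1.25 to 1.39). None of the 12 genes of the G3BP1 and stress granule list was 2-fold apart; the poly(A)-binding protein gene PABPC1 was 1.66-fold higher (1.63 to 1.69) and TIAL1 1.46-fold lower (1.35 to 1.60). The median of that list was −0.29, at percentile 8.29, and 0.11 after a correction for transcript GC content and length.

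The difference between the libraries reached far beyond the targeted RNA. Of 13532 genes with at least 1 CPM in either library, 2667 were at least 2-fold higher and 3135 at least 2-fold lower, together 42.9%. More than 10-fold differences were found for 497 genes that were higher and 646 that were lower. There were 41 genes with at least 1000 counts in the control library and 0 in the other, and 13 genes the other way round. CTNNA1, which encodes the alpha-catenin that ties cadherins to actin, had 5835 counts in the control library and 0 in the si-P53RRA library, at least 1322-fold lower. HOXB13, a homeobox gene of the posterior body and the prostate, had 0 counts and 10004 counts, at least 4905-fold higher. Across genes, which are not independent replicates, Pearson's r between the log2 CPM values of the libraries was 0.718 and Spearman's rho 0.769. With differences this wide, the libraries may hold different cell populations, as described in the last section. The gene and list values that follow are therefore not read as effects of the small interfering RNA.

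**Figure D1:**
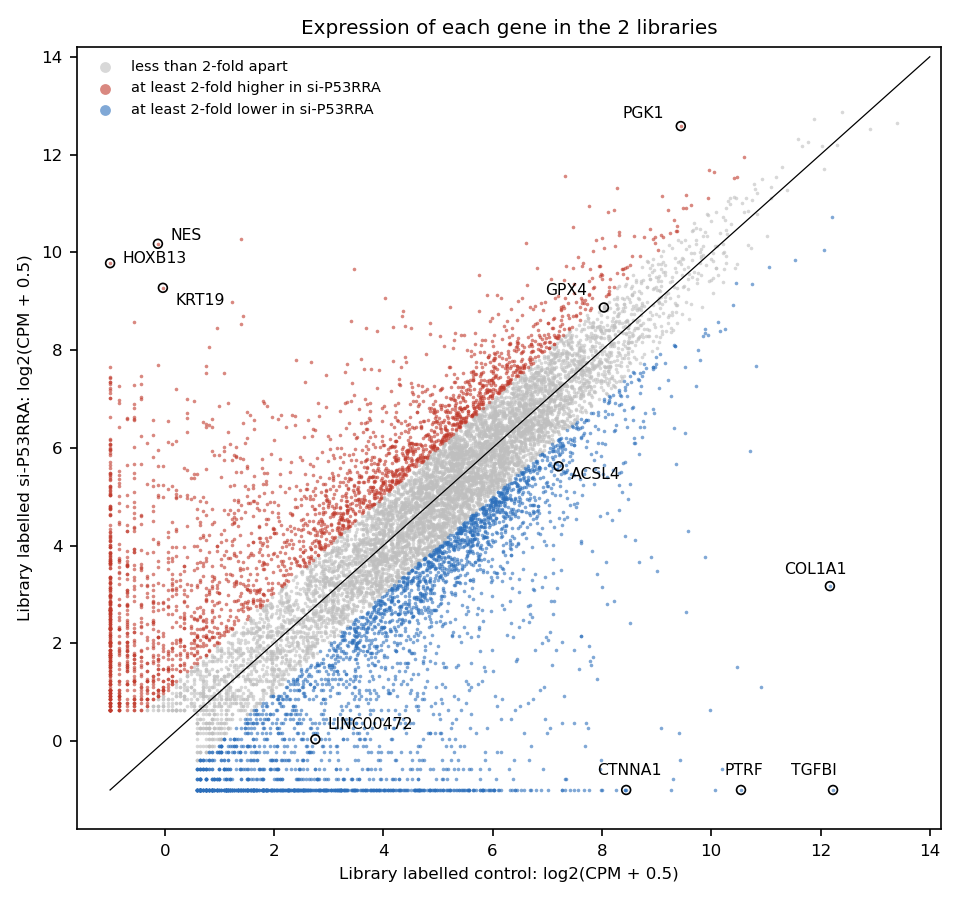
Expression of each gene in the library labelled control (x axis) and in the library labelled si-P53RRA (y axis), both as log2(CPM + 0.5), with genes at least 2-fold apart in colour. TGFBI, CTNNA1 and HOXB13 lie on the edges where one library has 0 counts, and LINC00472, 11.9-fold lower, lies among many genes that differ as much.

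The 12 genes with the largest decrease included genes of the extracellular matrix and of contractile or mesenchymal cells. TGFBI, a secreted matrix protein gene, had 80559 counts in the control library and 0 in the si-P53RRA library, at least 18257-fold lower. The caveolar coat gene PTRF (25060 counts against 0), the gelatinase MMP2 (18038 against 0), the surface glycoprotein THY1 (10323 against 0), the secreted Wnt modulator DKK3 (5773 against 0) and the myosin light chain MYL9 (5742 against 0) were likewise at 0. Their decreases were at least 5679-fold, 4088-fold, 2340-fold, 1308-fold and 1301-fold. Filamin C, FLNC, kept 2 counts and was 6703-fold lower (1855 to 55356), and the immediate early transcription factor EGR1, a near neighbour of CTNNA1 on chromosome 5, kept 1 count and was 7194-fold lower (1291 to 284172). CLDN11, a tight junction gene, was 2613-fold lower (894 to 12674), COL6A3, a collagen VI chain, 1160-fold lower (743 to 1927), and SERPINH1, a collagen chaperone, 963-fold lower (551 to 1864).

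The 12 genes with the largest increase included epithelial, neuronal, mucin and cancer-testis genes. The intermediate filament gene NES, known from neural progenitors, was 2769-fold higher (1344 to 6888), the simple-epithelium keratin KRT19 1297-fold higher (658 to 3004) and the neurotensin receptor NTSR1, with 3 counts in the control library, 2128-fold higher (728 to 10322). EEF1A2, a translation elongation factor of muscle and neurons, was 578-fold higher (417 to 825). The somatostatin receptor SSTR5, the cartilage link protein HAPLN1, the gel-forming mucin MUC5B, GLB1L2 and the keratin KRT75 had 0 counts in the control library and were at least 1121-fold, 961-fold, 906-fold, 905-fold and 835-fold higher. The cancer-testis genes CTAG2 and MAGEA6 were also at 0 there and at least 980-fold and 880-fold higher. MAGEA6 has near-identical relatives, so its reads may be split with them.

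Genes that mark epithelial and mesenchymal cells were compared as lists fixed beforehand. Of 26 listed epithelial genes, 17 reached 1 CPM in either library, of which 12 were at least 2-fold higher and 3 lower. CLDN4, a tight junction claudin, was 188-fold higher (136 to 268), the splicing regulator ESRP2 228-fold higher (97.1 to 703) and the placental cadherin CDH3, with 3 counts in the control library, 230-fold higher (78.2 to 1119). The 3 that were lower, named after their values were seen, were DSP, TJP1 and OCLN, with log2 changes of −5.63, −1.55 and −1.20. The median log2 change of the list was 2.21, above all 10000 random lists; it was 1.11 with no filter on low values and 1.40 with a pseudocount of 2.5 CPM, again above all random lists. Of 24 mesenchymal genes, 2 were higher and 18 lower, with fibronectin, FN1, 600-fold lower (412 to 911) and the basement membrane collagen COL4A2 at least 1162-fold lower. CDH11 (57 and 1129 counts) and SNAI1 (26 and 145 counts), also named after their values were seen, were the 2 that were higher. The median of the 24 genes was −3.14, below all 10000 random lists. In the list of fibroblast and endothelial markers, 2 of 11 were higher and 8 lower, with a median of −4.46 that was below all random lists. The 2 that were higher, named after their values were seen, were the endothelial genes KDR (0 and 61 counts) and PECAM1 (10 and 101 counts). The fibrillar collagen genes COL1A1 and COL3A1 were 543-fold (445 to 669) and 1112-fold (539 to 2766) lower, and the proteoglycan decorin, DCN, at least 176-fold lower. Of 7 luminal prostate genes, 2 were higher and 3 lower; SLC45A3, a solute carrier gene of the prostate, was 9.68-fold higher (7.42 to 12.8). That list had a median of −0.81 and a mean of 0.29, at percentile 10.9. Of 3 neuroendocrine genes, SCG2, a secretogranin, was at least 26.5-fold lower and none was higher, with a median of −0.94 at percentile 24.9. Only 2 leukocyte genes were measured, with lysozyme, LYZ, at 1 and 16 counts, and this list was too short for a percentile.

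**Figure D2:**
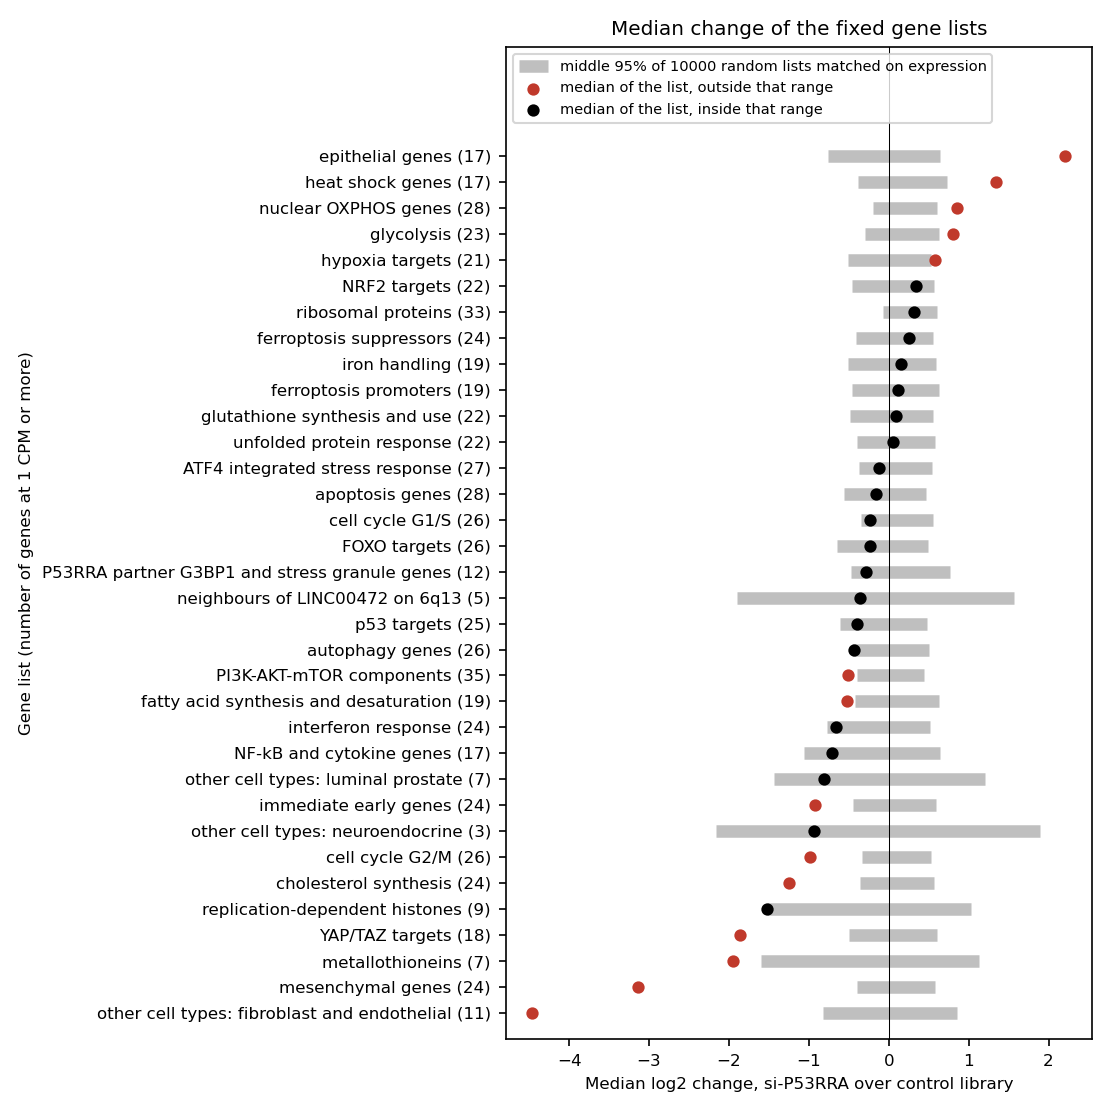
Median log2 change of each list fixed beforehand (x axis, si-P53RRA over control library) with the number of measured genes in parentheses on the y axis; grey bars span the middle 95% of 10000 random lists matched on expression. Of 34 lists with a percentile, 5 lie above that range, with epithelial genes highest at 2.21, and 9 lie under it, with fibroblast and endothelial genes lowest at −4.46.

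Targets of the Hippo pathway effectors YAP and TAZ were lower as a group, and immediate early genes went both ways with more of them lower. Of 18 YAP/TAZ targets, none was 2-fold higher and 12 were lower, with a median of −1.86 that was below all random lists. The receptor tyrosine kinase AXL was 774-fold lower (393 to 1793), AMOTL2 41.8-fold lower (33.2 to 53.3), CTGF 48.5-fold lower (40.5 to 58.5) and CYR61 39.8-fold lower (34.8 to 45.7). CTGF and CYR61 are also members of the immediate early list, in which 3 of 24 genes were higher and 11 lower, with a median of −0.92 at percentile 0.01. EGR3, at 1 count in the si-P53RRA library, was 75.5-fold lower (13.3 to 3007), while DUSP6 and MYC, picked after their values were seen, had log2 changes of 2.41 and 2.33.

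The series title names ferroptosis, and its genes went in both directions between these libraries. Of 24 ferroptosis suppressors, 4 were at least 2-fold higher and 3 lower, with a median of 0.25 at percentile 74.3. GPX4, the peroxidase that reduces lipid hydroperoxides, was 1.79-fold higher (1.71 to 1.86), while SLC7A11, the cystine importer, was 1.53-fold lower (1.34 to 1.75), and AIFM2, which regenerates reduced coenzyme Q, was 1.47-fold lower (1.27 to 1.71). The peroxiredoxin PRDX6 was 9.08-fold higher (8.77 to 9.41), the small heat shock protein gene HSPB1 4.16-fold higher (4.06 to 4.26) and DHODH, a pyrimidine synthesis enzyme in mitochondria, 2.96-fold higher (2.41 to 3.65). Of 19 ferroptosis promoters, 4 were higher and 3 lower, with a median of 0.11 at percentile 56.5 that became −0.02 when libraries were scaled on total counts and −0.13, at percentile 28.4, with no filter on low values. ACSL4, which loads polyunsaturated fatty acids into membranes, was 3.02-fold lower (2.76 to 3.32) and the haem oxygenase HMOX1 4.23-fold lower (3.54 to 5.08). The mitochondrial channel VDAC2 was 4.96-fold higher (4.79 to 5.13) and DPP4 2.45-fold higher (2.25 to 2.66). These values stand beside the losses of mesenchymal and fibroblast genes, with list medians of −3.14 and −4.46, in the same 2 libraries.

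Iron storage genes diverged from each other. FTH1, the ferritin heavy chain, was 1.79-fold higher (1.77 to 1.80), whereas FTL, the light chain, was 4.04-fold lower (3.97 to 4.12), and both have processed pseudogenes that can share reads. TFRC, the transferrin receptor that imports iron, was 1.69-fold higher (1.61 to 1.78), NCOA4, the ferritin autophagy receptor, 2.30-fold lower (2.14 to 2.47), and ACO1, which is the iron regulatory protein when it lacks its cluster, 2.45-fold lower (2.25 to 2.67). HFE, a partner of the transferrin receptor, was at least 40.1-fold lower. Of 19 iron handling genes, none was 2-fold higher and 5 were lower, with a median of 0.15 and a mean of −0.28, at percentile 64.2. Of 22 glutathione genes, 4 were higher and 6 lower, with a median of 0.10 (−0.03 on total counts and −0.09 with no filter on low values) and a mean of −0.57, at percentile 59.8. Among them the glutathione transferase GSTM1 and the transpeptidase relative GGT7 were at 0 in the si-P53RRA library, at least 133-fold and 50.3-fold lower. GPX3, the secreted peroxidase, kept 1 count and was 116-fold lower (20.6 to 4619), and MGST2 was 5.64-fold higher (4.48 to 7.18). Of 22 targets of NRF2, the transcription factor of the oxidative stress response, 5 were higher and 4 lower, with a median of 0.34 at percentile 85.8; EPHX1 was 3.03-fold higher (2.78 to 3.30) and AKR1C3 had 0 and 27 counts.

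The title also names AKT signalling, whose activity depends on phosphorylation that counts of RNA do not measure. AKT1 was 1.11-fold higher (1.07 to 1.15) and AKT2 was level at 1.00-fold (0.941 to 1.07). IGF1R, the insulin-like growth factor receptor, and IRS2, its adaptor, kept 2 counts each and were 274-fold (75.7 to 2269) and 247-fold (68.2 to 2045) lower, while the insulin receptor, INSR, was 50.1-fold higher (27.7 to 101). Of 35 components of the pathway, 5 were higher and 10 lower, with a median of −0.51 at percentile 0.735. That median became −0.12, at percentile 26.6, after the same correction. Targets of the FOXO factors, which AKT restrains, went both ways, with 7 of 26 higher and 9 lower and a median of −0.23 at percentile 29.1. Among them SESN3 was 27.6-fold higher (17.2 to 47.2) and CITED2 8.50-fold lower (7.70 to 9.40).

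CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was 2.37-fold lower (2.15 to 2.60), and MDM2, the ubiquitin ligase of p53, 1.22-fold lower (1.09 to 1.37). The p53 targets PHLDA3 and TP53INP1 were 67.5-fold lower (34.1 to 157) and at least 43.7-fold lower. SPATA18 was at least 9.75-fold lower. Of 25 genes of the p53 list, 1 was higher and 8 were lower, with a median of −0.40 at percentile 11.7. Of 28 apoptosis genes, 3 were higher and 5 lower, with a median of −0.16 at percentile 33.5 that became 0.03 after that correction; the death receptor FAS was 5.20-fold lower (3.36 to 8.42), the inhibitor BIRC2 3.39-fold lower (2.83 to 4.09) and the death receptor TNFRSF10A 8.51-fold higher (6.30 to 11.7). Of 26 autophagy genes, none was 2-fold higher and 7 were lower, with a median of −0.44 at percentile 3.13. The cargo receptor SQSTM1 was 3.40-fold lower (3.28 to 3.52), the lysosomal membrane gene LAMP1 2.66-fold lower (2.55 to 2.79) and MAP1LC3A at least 53.7-fold lower.

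Between these 2 libraries, genes of mitosis were lower as a group. Of 26 genes of the G2/M list, none was 2-fold higher and 13 were lower, with a median of −0.99 that was below all 10000 random lists. CENPE, a kinetochore motor, was 10.8-fold lower (8.41 to 14.1), the spindle pole gene ASPM 8.56-fold lower (6.85 to 10.8), the checkpoint kinase TTK 4.03-fold lower (3.44 to 4.76) and the phosphatase CDC25C 3.56-fold lower (2.85 to 4.50). Of 26 genes of the G1/S list, 2 were higher and 4 lower, with a median of −0.23 at percentile 7.02. The D-type cyclin CCND1 was 2.71-fold higher (2.59 to 2.82) and E2F2 3.11-fold higher (2.60 to 3.72), while the E-type cyclin CCNE2 was 11.2-fold lower (6.95 to 19.1) and CCND2 at least 16.3-fold lower. Of 9 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 7 were lower and none higher, with a median of −1.52 at percentile 2.56.

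Cholesterol synthesis genes were lower as a group. Of 24 genes of cholesterol synthesis and its control, 1 was at least 2-fold higher and 14 lower, with a median of −1.25 that was below all random lists. The sterol demethylation enzyme MSMO1 was 6.99-fold lower (6.16 to 7.95) and the sterol carrier STARD4 5.43-fold lower (4.52 to 6.56). Of 19 genes of fatty acid synthesis and desaturation, 1 was higher and 3 lower, with a median of −0.52 at percentile 0.955. After the correction for GC content and length that percentile was 14.6. The elongase ELOVL6 was 2.51-fold lower (2.16 to 2.91), the phosphatidate phosphatase LPIN1 2.20-fold lower (1.98 to 2.45) and AGPAT2 2.71-fold higher (2.52 to 2.91).

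Of 23 glycolysis genes, 8 were higher and 1 was lower, with a median of 0.80 at percentile 99.7. Phosphoglycerate kinase, PGK1, was 8.81-fold higher (8.64 to 8.99), hexokinase HK2 5.55-fold higher (5.13 to 6.02) and PDK1, which restrains pyruvate dehydrogenase, 3.12-fold higher (2.66 to 3.67), while the glucose transporter SLC2A3 was at least 303-fold lower. Of 21 hypoxia targets, 9 were higher and 5 lower, with a median of 0.58 at percentile 98.6, or 94.6 when at least 5 CPM was required. The carbonic anhydrase CA9, with 3 counts in the control library, was 554-fold higher (189 to 2688), and the oxygen sensor EGLN3 65.7-fold higher (34.3 to 145). ANGPTL4 was 10.2-fold higher (7.99 to 13.2), and the matrix cross-linking enzyme LOX was 56.5-fold lower (40.7 to 80.8). Of 28 nuclear genes of oxidative phosphorylation, 13 were higher and none was lower, with a median of 0.86 at percentile 99.9, or 0.48 at percentile 97.8 after the correction for GC content and length. Cytochrome c1, CYC1, was 8.16-fold higher (7.92 to 8.40), the ATP synthase subunit ATP5B 3.28-fold higher (3.22 to 3.34) and NDUFA1 3.35-fold higher (3.10 to 3.63). Of 33 ribosomal protein genes, 4 were higher and none lower, with a median of 0.31 at percentile 53.7.

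Among stress responses, the heat shock list stood highest. Of its 17 genes, 12 were at least 2-fold higher and 1 lower, with a median of 1.34 at percentile 99.99. HSF1, the transcription factor of the heat shock response, was 12.1-fold higher (11.5 to 12.7), and its neighbours DGAT1 and BOP1, picked after their values were seen, had log2 changes of 4.43 and 4.23. The inducible chaperone HSPA6 was 26.1-fold higher (13.4 to 58.2), CRYAB 12.7-fold higher (6.09 to 30.5) and HSPA1A, which shares reads with a near-identical copy, 4.80-fold higher (4.45 to 5.19). Of 22 genes of the unfolded protein response, 1 was higher and 2 lower, with a median of 0.05 at percentile 41.6 that became −0.08 on total counts; SDF2L1 was 4.50-fold higher (4.08 to 4.97) and calnexin, CANX, 2.94-fold lower (2.84 to 3.04). Of 27 genes of the ATF4 response, 3 were higher and 5 lower, with a median of −0.12 at percentile 18.5. The folate enzyme ALDH1L2 was 69.5-fold lower (31.7 to 190.0), the stress regulator NUPR1 10.7-fold lower (8.89 to 13.1) and VLDLR 5.35-fold higher (3.95 to 7.35). Of 7 metallothionein and zinc genes, 5 were lower and none higher, with a median of −1.95 at percentile 0.34 (−1.18 at percentile 4.15 when at least 5 CPM was required), and of −2.44 with genes at 0 set at their bound. MT2A was 5.50-fold lower (5.23 to 5.78) and MT1E at least 685-fold lower; these genes are close in sequence and can share reads.

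Innate immune genes were mixed. Of 24 interferon response genes, 3 were higher and 7 lower, with a median of −0.66 at percentile 5.36. OAS1, a sensor of double-stranded RNA, was 20.4-fold higher (14.8 to 29.1), while the sensor IFIH1 was 8.23-fold lower (4.32 to 17.6), MX1 12.7-fold lower (4.78 to 48.0) and XAF1 at least 17.7-fold lower. Of 17 genes of NF-kB and cytokine signalling, 4 were higher and 8 lower, with a median of −0.71 at percentile 9.63. That median was 0.18 when only genes with at least 5 CPM were used. TNFAIP2 was 33.9-fold lower (24.8 to 47.6), the cytokine IL11 41.3-fold lower (15.9 to 153), and IL1B, with 1 count in the control library, 73.5-fold higher (12.6 to 2962). The 13 genes of the mitochondrial genome were not in the table that was analysed. These values compare 2 libraries, and each list percentile describes these libraries without a p-value.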

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

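The correction for GC content and length and the treatments of genes at 0 were chosen after the result was seen. No paired analysis was possible because each group had 1 library, and for the same reason no replicate could be left out. LINC00472 was lower in the si-P53RRA library under each of the 6 alternatives run for it, with log2 changes from −3.34 with a pseudocount of 0.1 CPM to −1.53 with a pseudocount of 2.5 CPM. Of 26 alternative tallies of genes 2-fold apart, 23 were within 1.5 times the main tally. With at least 1 CPM required in both libraries, which leaves out genes present in 1 library, 1908 genes were lower, and a 4-fold threshold left 1129 higher and 1400 lower. Scaling on total counts moved the median log2 change of all genes from −0.06 to −0.18 and gave 2343 genes higher and 3463 lower; upper-quartile and median-ratio scaling moved it by less. Relative to that shift, the list medians that changed sign on total counts, those of ferroptosis promoters, glutathione genes and the unfolded protein response, were above the median of all genes under both scalings. With no filter on low values the first 2 of these were −0.13 and −0.09, under the median of all genes (−0.08). After the GC and length correction 2438 genes were higher and 2926 lower, and 4868 genes were 2-fold apart in the same direction before and after it. Of 305 list percentiles under alternatives, 16 in 6 lists moved into or out of the middle 95% of random lists. The percentile of the AKT pathway list was 26.6 after the correction, that of hypoxia targets 94.6 with at least 5 CPM, and that of metallothioneins 4.15 with at least 5 CPM. The histone list was under percentile 2.5 in several settings (0.13 after the correction), the interferon list reached 1.45 with no filter, and the fatty acid list left the low end at 3.07 with no filter. The mesenchymal median was −2.34 with no filter and −3.93 with at least 5 CPM, and the fibroblast and endothelial median −3.31 with a pseudocount of 2.5 CPM, each below all random lists. The metallothionein median was −3.48 with a pseudocount of 0.1 CPM and −0.65 with one of 2.5 CPM. The causes were not tested. Depth limits genes near 1 CPM, where a count of 0 allows 0.263 CPM in the si-P53RRA library.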

Other observations

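Gene families and neighbouring genes outside the fixed lists were looked at, and all of them were chosen after their values were seen. The test on CDH1 and EPCAM was chosen only after the result was seen. Among 24 collagen genes, 16 were at least 2-fold lower and 3 higher, with a median log2 change of −2.52. COL6A1 was the exception among the abundant ones, with 9297 counts in the control library and 10157 in the other. Of 5 lysyl oxidase genes, which cross-link collagen, 4 were lower. All 6 measured genes of the HOXC cluster were at 0 in the si-P53RRA library, among them HOXC6 with 403 counts in the control library and HOXC8 with 327. Of the 3 measured genes of the HOXB cluster, HOXB13 was higher, while HOXB2 (396 counts) and HOXB3 (78 counts) were at 0 in the si-P53RRA library. The 3 trefoil factors, small secreted proteins of mucous epithelia, had 0 counts in the control library and 754 (TFF1), 380 (TFF2) and 541 (TFF3) in the other. All 9 measured cancer-testis genes of the MAGE, CTAG, CSAG and PRAME families had 0 counts in the control library and were higher in the other; several are near-identical and can share reads. Of 126 long intergenic RNAs with LINC symbols, 43 were higher and 34 lower, so that LINC00472 was one of many that differed.

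Genes next to each other on a chromosome tended to differ in the same direction. On chromosome 14 the median log2 change was 0.80 over 307 genes, and in a run of 50 genes from TTC5 to GMPR2 35 were at least 2-fold higher. On chromosome 5 a run from ATG12 to CDC23 had a median of −1.20, with 29 of 50 genes lower. Around HSF1 and CYC1 on chromosome 8, BOP1 (log2 change 4.23), DGAT1 (4.43), FBXL6 (4.23), EXOSC4 (3.66) and MAF1 (2.36) were higher as well, although PARP10 (−5.62) was lower and GRINA (0.08) was level. HSF1 and CYC1 were leading members of the heat shock and oxidative phosphorylation lists. Near CTNNA1, EGR1 (−10.07), SIL1 (−4.73), REEP2 (−4.30), MATR3 (−1.15), KDM3B (−1.12) and ETF1 (−1.11) were lower by at least 2-fold. PAIP2 (−0.88) and SNHG4 (−0.53) were lower by less, HSPA9 (−0.03) was level and PROB1 (3.67) was higher.

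The first pattern is the number of genes 2-fold apart. Thinning the control library to the total of the other gave 5801 genes 2-fold apart, 99.98% of the main number. The GC and length correction gave a tally of 5364, or 92.5%, of which 4868 were 2-fold apart in the same direction before it. Thinning could not decide on depth, because the changes were already scaled to library size. In the counts simulated at these 2 library sizes, with Poisson error only, 0.139% of 12975 unchanged genes were called 2-fold apart. That rate argues against counting error at these depths as the main source. The corrected tally argues against GC content or transcript length as the main source. The SD of the medians of 169 runs of neighbouring genes was 0.445, 2.82 times the mean SD of shuffled orders (0.158), and none of 1000 shuffled orders reached it. After the GC and length correction the ratio was again 2.82. This met the outcome set beforehand for cells of different genomes in the libraries, by another line or a wrong label. It did not meet the outcome set for a knockdown in otherwise identical cells as the whole cause. Shuffled orders hold no shared regulation of neighbours, however, and neighbouring genes regulated together in different cell states may give the same picture. The spread alone cannot tell these explanations apart. Some shifts ran along a whole chromosome, seen only after the values were known. All runs of chromosome 14 had a positive median (0.529 to 1.385), with 121 genes at least 2-fold higher and 12 lower. Both runs of chromosome 18 were negative (−0.876 and −0.901). For these chromosomes the values argue against shared regulation of close neighbours as the only source. Other causes of a chromosome-wide shift were not separated from different genomes.

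The second pattern is that abundant genes of one library were at 0 in the other. A candidate explanation for CTNNA1 at 0 with high HOXB13 is that the si-P53RRA library came from PC-3, a prostate cancer line reported to lack CTNNA1. CAV1, reported as abundant in PC-3, was at 84.5 CPM, between the bound of 100 CPM set for that line and the 10 CPM set against it. CAV1 therefore did not decide for or against PC-3. No other gene was tested for this line, and the low values of CDH1 and EPCAM given below were not judged for it.

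The third pattern is the weak epithelial identity of the control library under a label of an epithelial line. Of 26 listed epithelial genes, 12 reached 1 CPM in the control library and 16 in the other. DU145 cells are known to express E-cadherin and EPCAM, yet the highest CPM of CDH1 or EPCAM in either library was 4.38. EPCAM had that value in the si-P53RRA library, from 50 counts, and had 0 counts in the control library. A highest value this low is the outcome set against DU145 cells in both libraries as labelled. The 2 genes and their bound were chosen after the result was seen, so this restates the pattern and is not a separate test of the label. Whether a change of state in culture could lower both genes was not tested, and no other line was tested for the control library. The lower LINC00472 in the si-P53RRA library had a log2 change of −2.76 after the GC and length correction. It may come from the small interfering RNA or from a difference between cell populations. With 1 library per group, and 16.0% of genes at similar expression lower by as much in the main values, these were not separated. The value of LINC00472 is therefore no check of the knockdown.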
